A study of Mus musculus with 6 samples.

How the data were processed

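The series consists of 6 dye-swapped 2-colour hybridisations to a spotted long-oligonucleotide mouse array. Per the labels, 3 pools of Pitx3 mutant ventral midbrain were each hybridised on 2 arrays against 1 wild-type reference pool, with the mutant once in Cy5 and once in Cy3. The arrays of a pool share both RNA extracts, so the pool was taken as the replicate (n = 3). Each pool joined several embryos, so the spread between pools holds both biological and technical differences. The reference is the only control RNA, and the test of the ratio against 0 leaves out the control's own spread.

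The deposited scanner files hold the intensity of each spot and of its local background in both channels. Per the protocol descriptions that came with them, slides were scanned on an Agilent instrument and spots were quantified with ImaGene. The authors' derived files hold intensity values for both dyes after print-tip loess without background subtraction, per the same descriptions. The product of both channels at each spot was the same in the raw and derived files (largest log2 difference 1.4e-05). The deposited series matrix holds log2 ratios. They were equal to the derived ratios turned to mutant over reference, within 5e-06, which settles their scale and direction and ties their rows to probes. The medians of its 6 columns lay between -0.0027 and 0.0018. Versions, and any statistical test by the authors, are not given in the sources used here.

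Computation started from the scanner files with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50, global loess with a span of 0.3 was fitted within each array with control spots at weight 0, and 3223 control spots were then left out of 34992. No probe had more than 1 spot left to average. Ratios were turned to mutant over reference, averaged over the 2 arrays of a pool and tested against 0 with lmFit and eBayes (2 residual and 2.74 prior degrees of freedom), with Benjamini-Hochberg adjustment over 31769 probes and an adjusted p under 0.05 as the threshold. The offset keeps dim probes quiet but shrinks all ratios, so folds are understated, most of all for dim genes. Brighter genes are touched too: En2's ratio divided by 2 was 0.39, and 0.45 with an offset of 0. The highest raw signal was 29536, and no spot was treated as saturated. The plan was to leave out spots flagged by the scanner software, but the files used here have no flag column, so all spots were kept.

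A probe counted as above background in a channel when its signal exceeded the mean local background by 2 background SDs. In at least 1 channel on all 6 arrays this held for 13882 probes (43.7%), and for 12636 probes it held in no channel of any array. Where a probe was above background on no array of the mutant or of the reference, the ratio is given with a bound. The bright side's mean over the pools was set against the dim side's, where each dim value was raised to the lowest signal among probes above background in that channel, on log2 channel values after loess and Aquantile scaling.

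Gene names came from the platform table for the series matrix rows. It gave 1 symbol for 26000 of the gene probes, several for 0 and none for 5769. Symbols were updated through the mouse RefSeq gene table of assembly GRCm38.p6: 23070 were current, 2865 were replaced through a synonym and 65 were kept as found. The arrays name no genome build, so that table served for names and gene order only, and no coordinates are given. Lists used 1 probe per gene, the one with the highest mean intensity, over 17865 genes.

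Before the data were examined, 29 gene lists (415 genes, 376 measured) and the rule for naming genes were fixed. The rule takes Pitx3, all measured members of the dopamine list, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with the same sign on all 6 arrays, and up to 4 members of each other list with the lowest p. As no probe passed, the 10 probes with the lowest p took the place of the rises and falls, as values only. Lists with at least 5 measured members were tested with camera (preset correlation 0.01, two-sided, adjusted over the lists), with camera using an estimated correlation and fry as alternatives. Camera with an estimated correlation rests on the 2 residual degrees of freedom. It could thus hardly pass after adjustment, and a call lost there decides nothing about a list. Members were also counted after adjustment over the list alone. These counts were not adjusted across the 29 lists, and a gene on several lists, such as Aldh1a1, is counted in each from the same probe.

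The steps from arrays to calls were tested on simulated data with 200 changed probes among 31769 in each of 10 runs, for the comparison of mutant pools with the reference. With spreads drawn from the fitted prior, 90.7% of changes of 0.25 (log2) were called, 98.4% of changes of 0.5 and 99.8% of changes of 1, and 4.8% of all calls were false. With each probe's own moderated spread, 98.5% of changes of 0.25 were called and 9.4% of calls were false, above the nominal level. The simulation held no shared differences between pools. With 200 changed probes per run, the adjusted threshold is easier to reach than with few changed probes. These rates therefore do not tell how many changes were missed in the data, where En2 at 0.79 and Slc18a2 at -0.36 did not pass. Alternatives covered the background correction, the loess, scaling between arrays, the authors' values, a filter on dim probes, the replicate structure, a trend in the spread, each dye orientation alone and each pool left out.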

Results

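Gene expression was measured in the ventral midbrain of E14.5 mouse embryos that lacked the homeobox transcription factor Pitx3, against tissue from wild-type embryos. The ventral midbrain at this stage holds the young dopaminergic neurons of the later substantia nigra and ventral tegmental area. There were 3 mutant pools of 3 midbrains each, and each pool was hybridised on 2 arrays with the dyes exchanged. The other channel of all 6 arrays held 1 wild-type reference RNA from 10 midbrains. The arrays carried 31769 gene probes, and the median spot signal per array lay between 70.6 and 77.5 in Cy5 and between 46.2 and 50.4 in Cy3, over local backgrounds of 58 to 62 and 38 to 41. From 46.1% to 51.7% of gene probes were above background in the mutant channel and from 47.5% to 54.6% in the reference channel. On 12 quality-control probes with 16 spots each, the log2 ratio of a pool had a median SD of 0.029 between spots. All ratios below are mutant over reference on the log2 scale, as mean ± SD over 3 pools, and the small number of pools and the single reference limit their precision.

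The comparison asked which transcripts of the ventral midbrain depend on Pitx3. Slc18a2, the transporter that loads dopamine into vesicles, had a ratio of -0.36 ± 0.03, 0.78 times the reference level, and was below 0 in all 3 pools. Like Pitx3 it lies on chromosome 19. En2 and En1, homeobox genes of the midbrain and isthmus, stood at 0.79 ± 0.11 and 0.69 ± 0.26, which is 1.72-fold and 1.61-fold. The neuropeptide genes Cck and Nts stood at 0.41 ± 0.06 and 0.37 ± 0.11, and all 4 of these genes were above 0 on all 6 arrays. The offset added to every spot pulls all these ratios towards 0, so the folds are understated. With each pool as 1 replicate, none of the 31769 probes passed limma's test after adjustment over all probes. Slc18a2 had the lowest adjusted p, 0.19.

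At an unadjusted p under 0.05 there were 1548 probes, 783 higher and 765 lower, where chance alone gives 1588. The count rested on the model and on what counted as a replicate. With the 6 arrays as separate values, a dye term and the pool as a random block, 18 probes passed, 9 higher and 9 lower. With 6 independent arrays and a dye term 29 passed, 11 higher and 18 lower. With an intensity trend in the spread 11 passed, 5 higher and 6 lower. These 3 fits shared 9 probes: Cck, En2, Nts, Klf4 and Cbln1 on the higher side and Slc18a2, Aldh1a1, Nhlrc2 and 1 unnamed probe on the lower side. The fits with 18 and 29 probes count both arrays of a pool, which share their RNA extracts, and so depart from n = 3. The block fit allowed for this only through 1 correlation for all probes, 0.16. All 3 fits use the same 6 arrays and the same reference, so their overlap is not independent support. Without pool 3, 1543 probes passed, 638 higher and 905 lower, and 25% of them had the same sign in pool 3. The wild-type RNA was a single pool, so a gene that happened to be off in that pool would shift all 3 ratios together.

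The Pitx3 probe itself had ratios of 0.04, 0.01 and 0.03 in pools 1, 2 and 3. Its spots were not well above background in either channel on any array. It thus shows nothing about the genotype of the pools, and whether it lies in the part of the gene that was removed is not given in the sources used here.

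**Figure D1:**
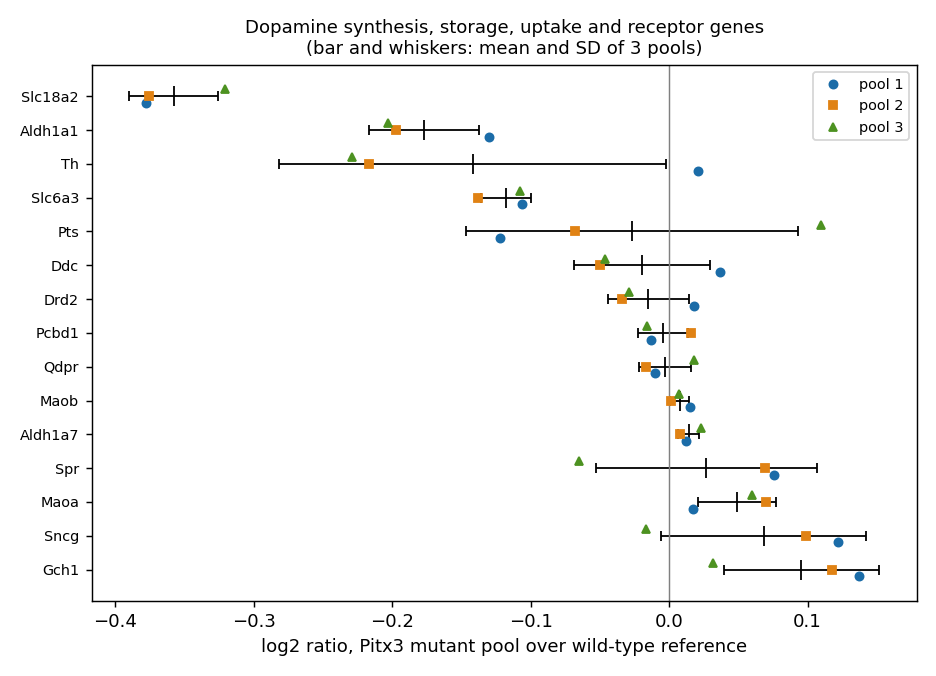
Log2 ratio of mutant pool over wild-type reference (horizontal axis) for the 15 measured genes of dopamine synthesis, storage, uptake and reception (vertical axis); symbols are the 3 pools, the bar and whiskers their mean and SD. Slc18a2, Aldh1a1 and Slc6a3 lie below 0 in all 3 pools, while Th ranges from -0.23 to 0.02.

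Among the genes of dopamine synthesis, storage, uptake and reception, 15 of 17 were measured. None passed over all probes. Adjusted over the list alone, Slc18a2, Aldh1a1 and Slc6a3 passed as lower and Gch1 as higher, and 11 did not pass. Aldh1a1, which makes retinoic acid and marks a subset of dopaminergic neurons and also lies on chromosome 19, stood at -0.18 ± 0.04. It was above background in the reference on all 6 arrays and in the mutant on none, so only a bound holds, at least 1.08-fold lower. Slc6a3, the dopamine reuptake transporter, stood at -0.12 ± 0.02 and was above background only in the reference, on 2 arrays, with a bound of at least 1.01-fold lower. Both ratios are pulled towards 0 by the offset added to every spot. Gch1, the entry enzyme of tetrahydrobiopterin synthesis, stood at 0.10 ± 0.06, but at -0.07 on the arrays with the mutant in Cy5. Th, the rate-limiting enzyme of dopamine synthesis, stood at 0.02, -0.22 and -0.23 in the 3 pools and did not pass.

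The list did not pass the set test for a shift in 1 direction (camera adjusted p = 0.19), and its remaining members did not pass either. It did pass a test of whether members change in either direction (fry's mixed test, adjusted p = 0.018). Sncg stood at 0.07 ± 0.07, Maoa at 0.05 ± 0.03 and Spr at 0.03 ± 0.08, and these 3 stood at -0.0071, -0.02 and -0.05 with median centring in place of loess. Pts stood at -0.03 ± 0.12. Ratios of Ddc, the next enzyme after Th, and of the receptor gene Drd2 were -0.02 ± 0.05 and -0.02 ± 0.03. Qdpr, Pcbd1, Maob and Aldh1a7 lay between -0.004 and 0.01. Of these, Aldh1a7 was not well above background on any array.

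The transcription factors of midbrain dopaminergic neurons had 17 of 18 members measured. En2, En1 and Foxa1 passed as higher adjusted over the list alone, and 14 did not. Foxa1 stood at 0.21 ± 0.13, with 0.28 in pools 1 and 2 and 0.06 in pool 3. En1 differed in the same way, with 0.82 and 0.86 against 0.39 in pool 3. Nr4a2, which encodes Nurr1, stood at -0.13 ± 0.09 and did not pass. In the set test the list lay above other genes (camera adjusted p = 0.0012), with a mean of 0.12 and a median of 0.03. With an estimated correlation this call was lost (adjusted p = 0.58).

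Of the genes earlier reported as targets of Nurr1 and Pitx3, all 12 were measured. Slc18a2, Aldh1a1 and Slc6a3 passed as lower adjusted over the list alone, Dlk1 passed as higher, and 8 did not pass. Dlk1, which encodes a membrane protein related to Notch ligands, stood at 0.14 ± 0.05. The list lay below other genes (camera adjusted p = 0.0029), and not with an estimated correlation (adjusted p = 0.58). Bdnf, also on the list, was not well above background in either channel.

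Genes enriched in the substantia nigra and in the ventral tegmental area were followed separately. In the nigral list of 14 measured genes, Aldh1a1 and Slc6a3 passed as lower and Anxa1 as higher adjusted over the list alone, and 11 did not. Anxa1 stood at 0.06 ± 0.01. In the tegmental list of 14 measured genes, Cck and Nts passed as higher and Slc17a6, the vesicular glutamate transporter, as lower, and 11 did not. Slc17a6 stood at -0.15 ± 0.09, and at 0.02 on the arrays with the mutant in Cy3. A second, dimmer Cck probe had a ratio of -0.01 and was above background in the mutant on 3 arrays. Neither list passed the set test (camera adjusted p = 0.62 for the nigral and 0.081 for the tegmental list).

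Retinoic acid genes had 21 of 23 members measured, and 2 passed adjusted over the list alone, both lower: Aldh1a1 and Crabp1. Crabp1, a cellular retinoic acid binding protein gene, stood at -0.08 ± 0.02. Meis2 stood at -0.33, -0.28 and 0.07 in the 3 pools and did not pass. The list did not pass the set test (camera adjusted p = 0.42).

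**Figure D2:**
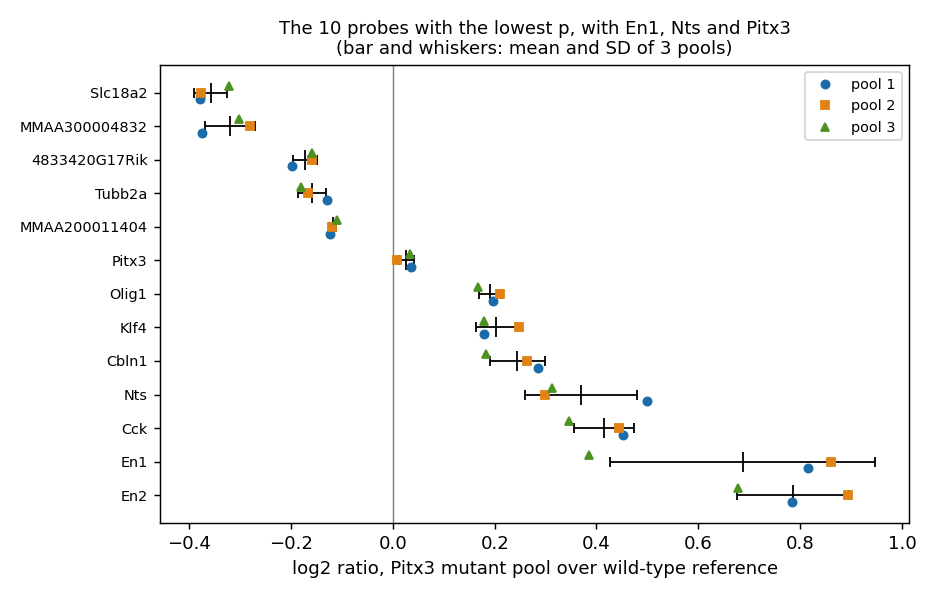
Log2 ratio of mutant pool over wild-type reference (horizontal axis) for the 10 probes with the lowest p and for En1, Nts and Pitx3 (vertical axis); symbols are the 3 pools, the bar and whiskers their mean and SD. En2 lies between 0.68 and 0.90 and En1 between 0.39 and 0.86, while Pitx3 lies within 0.04 of 0.

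Beyond Slc18a2, En2 and Cck, the 10 probes with the lowest p are given as values only, since none passed over all probes. Olig1, a transcription factor of the oligodendrocyte lineage, stood at 0.19 ± 0.02, Klf4 at 0.20 ± 0.04 and Cbln1, which encodes a synaptic organiser, at 0.24 ± 0.05. The uncharacterised gene 4833420G17Rik stood at -0.17 ± 0.02 and a probe of the beta-tubulin gene Tubb2a at -0.16 ± 0.03. The brighter probe of Tubb2a had 0.02, -0.04 and -0.23 in the 3 pools. Dimmer probes of Cbln1 and 4833420G17Rik stood at 0.08 ± 0.02 and -0.09 ± 0.09. Of 2 probes without a gene name, MMAA300004832 stood at -0.32 ± 0.05, was above background only in the reference and was at least 1.15-fold lower, with its ratio also pulled towards 0 by the offset. The other, MMAA200011404, stood at -0.12 ± 0.0066.

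Neurons of other transmitter types were also measured. The GABAergic list had 12 measured genes, of which Slc32a1, the vesicular GABA transporter, passed as higher adjusted over the list alone at 0.21 ± 0.06, and 11 did not. Gata2 had ratios of 0.19, 0.31 and -0.04 and Gata3 of 0.13, 0.25 and -0.02. In the serotonergic list of 5 measured genes, Tph2 and Slc6a4, for serotonin synthesis and reuptake, passed as higher at 0.14 ± 0.05 and 0.16 ± 0.09. Slc6a4 was above background only in the mutant, on 4 arrays, and was at least 1.06-fold higher. Both lists lay above other genes (camera adjusted p = 0.0071 and 0.038), and neither did with an estimated correlation (adjusted p = 0.58). In the glutamatergic and red nucleus list, 1 of 10 genes, Nkx6-1 at 0.12 ± 0.07, passed as higher and Slc17a6 as lower. Lhx9 on that list had -0.81, -0.42 and -0.12 in the 3 pools and did not pass. None of the 8 oculomotor and cholinergic genes passed, with Isl1 at -0.63, -0.54 and 0.05. Neither of these 2 lists passed the set test (camera adjusted p = 0.83 and 0.98).

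Non-neuronal cells were represented by several lists. In the oligodendrocyte and astrocyte list of 11 measured genes, Olig1 and Pdgfra, a receptor of oligodendrocyte precursors, passed as higher adjusted over the list alone, with Pdgfra at 0.11 ± 0.02, and 9 did not pass. No member of the microglia list (12 measured) or the meninges list (16 measured) passed, yet these 3 lists lay above other genes (camera adjusted p = 0.0097, 0.0084 and 0.0084). Their mean ratios were small, 0.04, 0.02 and 0.02, and no call held with an estimated correlation (adjusted p = 0.58 for each). C1qb, a microglial complement gene, stood at 0.07 ± 0.04. Col5a1, a meningeal collagen gene, stood at 0.04 ± 0.03, and at -0.02 with median centring in place of loess. None of the 13 endothelial genes passed. One erythroid gene of 11, the transferrin receptor gene Tfrc, passed as lower at -0.11 ± 0.05, though it was near 0 (0.0085) on the arrays with the mutant in Cy3. Actc1 was the 1 of 14 muscle and cartilage genes to pass, at 0.07 ± 0.01. These 3 lists did not pass the set test (camera adjusted p = 0.19, 0.77 and 0.33). Tissue next to the midbrain was represented by 15 hypothalamic and 10 pituitary genes, and the eye by 14 lens crystallin genes. No member passed, and none of the 3 lists did (camera adjusted p = 0.88, 0.41 and 0.98).

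Among general programmes, the list of neuronal differentiation and synapse genes lay above other genes (camera adjusted p = 0.0019), with a mean of 0.03 and none of 19 members past the test. That call was lost with an estimated correlation (adjusted p = 0.58), and the mean was -0.04 with median centring in place of loess. In pools 1, 2 and 3 the list mean was 0.055, 0.053 and -0.007. Stmn2 stood at 0.06 ± 0.04, and at -0.04 with median centring. Axon guidance (23 measured), neural progenitors and cell cycle (19), floor plate, Wnt and Shh signalling (15), apoptosis (12) and neurotrophic factors (13) had no member past the test and did not pass as sets (camera adjusted p = 0.90, 0.17, 0.061, 0.34 and 0.88). Spon1, a floor plate gene, stood at 0.30 ± 0.15 and Cdkn1a at 0.10 ± 0.10. Nes, a progenitor gene, had 0.33, 0.26 and -0.09 in the 3 pools. In the stress list of 14 genes, Atf4 passed as lower adjusted over the list alone at -0.08 ± 0.02, but stood at 0.02 on the arrays with the mutant in Cy5. In the hypoxia and glycolysis list of 13 genes, Egln3 passed as higher at 0.13 ± 0.06 and Vegfa as lower at -0.06 ± 0.01, while 3 other Vegfa probes lay between -0.01 and 0.01. Neither list passed the set test (camera adjusted p = 0.52 and 0.34).

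Pitx3 lies on chromosome 19, and 29 of 30 of its neighbours there were measured. As3mt, an arsenite methyltransferase gene, passed as higher adjusted over the list alone at 0.18 ± 0.04, and its dimmer probe stood at 0.12 ± 0.03. The other 28 did not pass, among them Gbf1 at 0.29 ± 0.16, and the list did not pass the set test (camera adjusted p = 0.29). Of the sex-linked genes only Xist was measured, at -0.01 ± 0.03. Its spots were above background on 1 array in the reference and on none in the mutant.

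**Figure D3:**
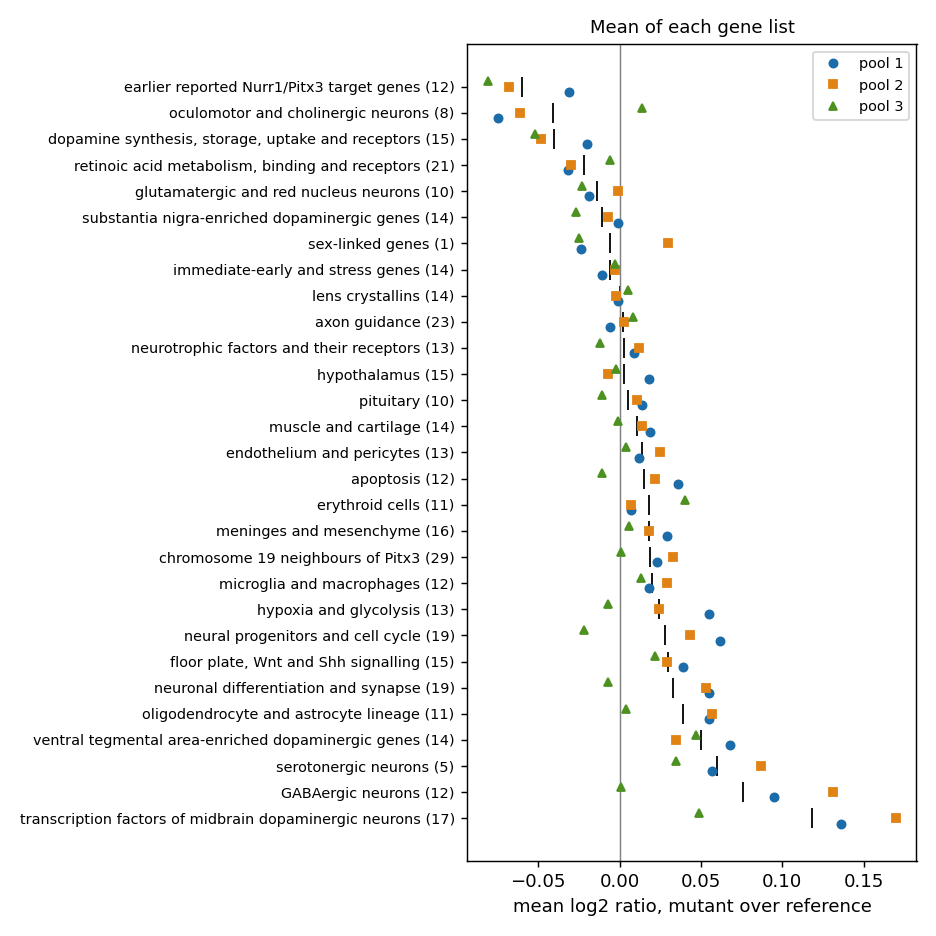
Mean log2 ratio over the measured members of each of the 29 gene lists (horizontal axis; number of members in brackets on the vertical axis); symbols are the 3 pools and the bar is their mean. The list means lie between -0.06 and 0.12, and for the GABAergic list pool 3 lies at 0.001 where pools 1 and 2 lie at 0.10 and 0.13.

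Over the 28 lists large enough for a set test, 8 passed camera with its preset correlation, 7 of them higher and 1 lower, and none with an estimated correlation. The estimate was 0.33 for the transcription factor list, above the preset 0.01. For the microglia list it was -0.079, below the preset, yet camera's unadjusted p rose from 0.0017 to 0.081. The lost calls therefore do not show that the members of a list were correlated. The test, median and mean differed in sign for 4 lists that did not pass: the glutamatergic list (mean -0.01, median 0.005, test upward), the oculomotor list (mean -0.04, median -0.001, test upward), the hypothalamic list (mean 0.003, median -0.004, test downward) and the lens crystallin list (mean 0, median -0.001, test upward).

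The pools themselves differed. Across probes, which are not independent replicates, the ratios of pools 1 and 2 correlated (r = 0.59), while pool 3 correlated with pool 1 at -0.21 and with pool 2 at -0.19. Isl1, Meis2, Gata2, Gata3, Nes and Nkx6-2 were among the named genes that stood apart in pool 3, with Nkx6-2 at 0.43, 0.42 and 0.01. The dye had a larger imprint than the genotype. For 8123 probes the mean Cy5 over Cy3 ratio differed from 0 (limma, adjusted p under 0.05), 4107 towards Cy5 and 4016 towards Cy3. Arrays with opposite dyes correlated between -0.60 and -0.17 across probes, and arrays with the same dye between 0.38 and 0.72. The mean of the 2 arrays of each pool removes this term.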

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

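The tests of pool 3 were chosen only after its ratios had been seen to differ from those of the other pools. The pool 3 array with the mutant in Cy5 had a median Cy3 signal of 46.2, where the nearest of the other 5 arrays had 49.1, a gap of 0.69 of the whole range. Its median Cy3 background was 38 against 40 for the nearest array, a gap of 0.67 of the range. Both gaps lie beyond Dixon's critical value for 6 arrays. Chance gives about 1 such result in 20 groups, and 7 array measures were examined. Cy3 held the reference RNA on this array.

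Pool 3 differed from pools 1 and 2 in many genes: Dlx1 had -0.90, -0.94 and 0.05 in pools 1, 2 and 3, Dlx2 had -0.46, -0.42 and 0.02, and Isl1 had -0.63, -0.54 and 0.05. The tables argue against a fault of a single array or a dye effect, since the difference between pool 3 and the mean of pools 1 and 2 correlated across probes at r = 0.56 between the 3 arrays with the mutant in Cy5 and the 3 with the mutant in Cy3, where faults of separate arrays alone give 0. A different sex mix is argued against as the whole cause, since the difference was not confined to sex-linked genes. Over 25032 probes of autosomal genes, its variance shared by both dye orientations was 12.4 times that of the difference between pools 1 and 2. With 1 chromosome left out this was 11.7 to 13.2 times, where 3 unrelated pools give 1. Pool 3 was picked because it stood apart, so a ratio above 1 was likely beforehand and its size is not independent support. A different share of other tissue in the dissection may still contribute and cannot be told apart from a difference between embryos. Among the lists of other cells and tissue fixed beforehand, the largest difference was that of GABAergic genes. Its median was -0.07 with an interval of -0.23 to 0, too wide to decide. The forebrain and diencephalon list, which holds Dlx1 and Dlx2, was not among the lists compared. RNA quality, amplification and a mixed-up sample were not tested, the Pitx3 probe cannot show the genotype of pool 3, and the labels do not say whether the pools came from separate litters. Every mean and SD over 3 pools includes pool 3. Beyond the sex mix and the share of other tissue, no biological explanation was tested, as the labels give no trait that separates the pools.

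Turning the sign of 1 pool at a time gives 4 sign patterns, so the share of patterns with a result as large is never under 0.25. Of these, 2, counting the real one, gave 1548 or more probes at an unadjusted p under 0.05. The highest other count was 4039, with pool 3 turned, which points to a structure of the samples: the difference between pool 3 and the others is shared by more probes than the common shift of all 3 pools.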

How the results depend on the processing

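No alternative was added after the data were seen. The alternative that keeps spots marked by the scanner software was not run, as the files used here have no flag column. No probe passed limma's test with no background correction, an offset of 0, print-tip loess, median centring, scaling between arrays, the authors' values, a filter on dim probes, or genes in place of probes. With 6 arrays, a dye term and the pool as a random block 18 probes passed (9 higher, 9 lower). With 6 independent arrays and a dye term 29 passed (11 higher, 18 lower), and with an intensity trend 11 (5 higher, 6 lower). On the arrays with the mutant in Cy5 312 passed (83 higher, 229 lower) and on those with the mutant in Cy3 430 (309 higher, 121 lower), where dye bias is not averaged out. Leaving out 1 pool gave 0 to 1543 probes, 0 to 638 higher and 0 to 905 lower, with the highest counts without pool 3 and 0 without pool 1 or pool 2. The lists past camera, 8 as reported, came to 0 with median centring, 5 with an intensity trend, 3 with the mutant in Cy5 and 1 in Cy3, 5 to 7 with 1 pool left out (5 without pool 3), and 0 with an estimated correlation or with fry's test of movement in 1 direction, while 9 passed fry's mixed test, which asks whether members change in either direction. Among those 9 were the dopamine, nigral, retinoic acid, oculomotor and stress lists, which did not pass camera. The lists past camera came to 12 with the authors' values, 11 with the pool as a random block, 10 with 6 independent arrays, 9 with the mean of a gene's probes, 7 with scaling between arrays, 6 with the filter on dim probes, and 8 with no background correction, an offset of 0 or print-tip loess. The dye effect was seen in 13874 probes with no background correction.

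The Pitx3 probe, not above background on any array, stood at -0.02 with the mutant in Cy5 only and at 0.32 with an offset of 0. Among named genes with an unadjusted p under 0.05, or past the threshold in the alternative, direction reversed with median centring for Maoa (-0.02), Ntrk3 (-0.0073), Stmn2 (-0.04), Elavl4 (-0.05), Nefm (-0.08), Pecam1 (-0.06), Col5a1 (-0.02) and, as a list, for neuronal differentiation and synapse genes (-0.04). It reversed with the mutant in Cy5 only for Gch1 (-0.07), Corin (-0.0022), Atf4 (0.02) and Cuedc2 (0.03), and in Cy3 only for Slc17a6 (0.02), Elavl4 (-0.06) and Tfrc (0.0085). The cause was not tested. Of 1805 comparisons of named genes over 15 settings, 111 passed the threshold only in the alternative, 14 reversed as above, and of the rest 1445 moved by no more than the SD of the pools and 235 by more. Of these 235, 75 came with an offset of 0, the most of any setting. Counting genes at any p, the sign changed in 77 comparisons, 21 with median centring, 18 with the mutant in Cy5 only and 17 in Cy3 only. Of 498 list comparisons over 18 settings, 427 stayed, 53 lost and 17 gained a call, and 1 reversed. Signal over background limits dim genes: 12636 probes were above background in no channel of any array.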

Other observations

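The chromosome 19 test was chosen only after its result was seen, and the isthmus and forebrain lists were chosen after the probes with the lowest p had been seen, before their own values were.

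En1, En2 and Cck were higher than the reference on every array, without passing limma's test over all probes. More isthmus or hindbrain tissue in the mutant pools would raise its other genes too, yet the median of 9 such genes above background, of 20 listed, was 0.01 with an SD of 0.06, against 0.39 for En2's ratio divided by 2. Tph2 was the highest of them at 0.14 and Gbx2 the lowest at -0.09. Several of the 9 were dim, but with an offset of 0 the median was 0.02 (SD 0.15), against 0.45. These 9 genes argue against such tissue as the source of En2's whole rise only. A smaller share is not excluded: Tph2 and Slc6a4 of the serotonergic list were above 0 in all 3 pools. That list also lay above other genes (camera adjusted p = 0.038). Dye bias is argued against by the smallest ratio of the 3 genes on a single array, 0.31 for Cck, with 0.35 for En1 and 0.61 for En2. Less forebrain tissue in the mutant pools stays open and cannot be told apart from an effect of the genotype: the median of 14 such genes above background, of 25 listed, was -0.04 (95% bootstrap interval -0.09 to -0.01), with 11, 9 and 9 of the 14 negative in pools 1, 2 and 3. That interval lay above the limit of -0.1 set beforehand, but the members went both ways, from -0.60 for Dlx1 to 0.11 for Irx3 (SD 0.18), so their median decides nothing. Both extremes came from pools 1 and 2, with Dlx1 at -0.90, -0.94 and 0.05 and Irx3 at 0.20, 0.18 and -0.06 in pools 1, 2 and 3. Tcf7l2 stood at -0.49, -0.23 and -0.15 in the 3 pools and Lhx2 at -0.17, -0.08 and -0.03. In pool 3, Dlx1, Dlx2 and Dlx5 stood at 0.05, 0.02 and 0.03, yet En2, En1 and Cck stood at 0.68, 0.39 and 0.35. The rise in that pool thus did not go with lower levels of these Dlx genes, while Tcf7l2 was below 0 in all 3 pools. An odd level in the single reference pool was not testable.

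Genes of chromosome 19, which carries Pitx3, made up 12 of the 100 genes with the lowest p, where the chromosome holds 613 of 17818 genes, 3.4% (odds ratio 3.9, interval 1.9 to 7.2, Fisher's exact p = 0.00016, two-sided, 0.0033 adjusted over 20 chromosomes). All 12 were among the 307 genes nearest to Pitx3 in gene order and none among the other 306 (Fisher's exact p = 0.00044). Within that part they lay from 15 genes (As3mt) to 201 genes (Aldh1a1) away. They included Slc18a2 at -0.36, Aldh1a1 at -0.18, Nhlrc2 at -0.20, Bloc1s2 at 0.19 and As3mt at 0.18, with 3 higher and 9 lower. Without Slc18a2 and Aldh1a1, 10 remained (Fisher's exact p = 0.0023). The list of 29 measured close neighbours, fixed beforehand, did not pass the set test for a shift in 1 direction (camera adjusted p = 0.29). Strain variation carried along with the targeted gene is a candidate explanation, through expression or through probe binding, and it could also touch Slc18a2 and Aldh1a1. Of the 4 sign patterns of the pools, 1, the real one, gave as many as 12 such genes, and the highest other gave 6, but 4 patterns are too few for a share under 0.05.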
